A study of Mus musculus with 19 samples.

How the data were processed

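RNA from whole ovaries of mice aged 2 months was measured on 19 Affymetrix Mouse Genome 430 2.0 arrays. The groups were 8 control arrays from mice heterozygous for both genes, 4 arrays of mice lacking Dhh (Dhh KO), 4 arrays of mice lacking Ihh (Ihh KO) and 3 arrays of mice lacking both genes (DKO), with deletion in the ovary per the labels. Total RNA was purified with a PicoPure kit, amplified with the WT-Ovation Pico system and labelled with biotin through the Encore Biotin Module, per the labels' protocols. The deposited table holds 1 linear intensity per probe set and array, called a MAS5 signal per the submitters' processing notes, with no version given in the sources used here. The authors' scaling could be read from the values: the mean signal after trimming 2 percent of the probe sets at each end was 500 on every array.

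The table held 45101 probe sets, 64 of them Affymetrix controls. Outside the controls, 34945 probe sets were assigned 1 gene and 932 several genes, and 9211 probe sets had no gene listed, controls included. Gene symbols came from the probe annotation supplied with the values. They were looked up by Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, used for names only: 34741 of the single-gene probe sets matched and 0 symbols changed. No coordinates are given, since the positions of the probes relative to the deleted exons are not given in the sources used here.

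Values were taken as deposited, without a second normalization, as log2 of the signal plus 7.02, the 10th percentile of all signals. Probe sets with a mean log2 value under the 40th percentile (6.26, a signal of 69.4) were left out. Each gene was represented by its single-gene probe set with the highest mean, which left 12379 genes. Differences between groups were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with an intensity trend, two-sided) in 1 model of the 4 group means over all 19 arrays, called the fit of group means, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. There were 7 comparisons: each mutant group against the controls, the 3 pairs of mutant groups, and non-additivity, the log2 value of DKO minus Dhh KO minus Ihh KO plus control. Figures were drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

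Gene lists for ovarian cell types and pathways were fixed together with the groups, tests and alternatives before the data were examined. The 22 lists held 221 genes, of which 20 had no single-gene probe set and 33 lay under the filter, and the 18 lists with at least 3 tested members were tested with limma's camera at a preset correlation between genes of 0.01. List tests were repeated with an estimated correlation and with fry. Members past the threshold were also counted after adjustment over the list alone.

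The genes named were fixed by rule. For each mutant group against control these were Dhh, Ihh and the Hedgehog target genes, the 10 largest rises and 10 largest falls among called genes with every mutant array on the same side of the control mean, and up to 4 members with the smallest p of each list with a called member. The other comparisons take 5 rises and 5 falls. Predicted genes known by a clone or Gm number were skipped. Genes named from a fit added later follow the same rule, and any others are named as chosen after their values were seen.

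The arrays fell into 2 sets by their hybridization controls, control arrays 1 to 4 with the DKO arrays and control arrays 5 to 8 with both single knockouts, and the labels do not mention them. The deviations of control arrays from the means of their set also matched across sets, 1 with 5, 2 with 6, 3 with 7 and 4 with 8 (across genes, r from 0.538 to 0.771; other matches from -0.635 to 0.162). Genes are not independent replicates in these correlations. A fit with the set as a block, and with a correlation shared by the matched controls (0.654, or 0.648 without the array labelled Ihh KO 4), was therefore added after seeing the data. It is called the blocked fit, and its list tests used the version of camera that ranks genes by their statistics. Numbers shared in the labels were checked across groups: for DKO and Dhh KO the deviations of arrays with the same number correlated at 0.204, 0.133 and 0.177, and no other groups had every pair above 0.1. Control and Dhh KO arrays of the same number correlated at 0.289, 0.0976, 0.430 and 0.216. Any pairing by number would come from the values alone, and the labels do not explain the numbers.

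Alternatives fixed in advance were quantile normalization, median centring, a pseudocount of 29.4 (the 25th percentile) or none, no filter (18193 genes), a filter at the 60th percentile (9517 genes), 23341 probe sets tested one by one, the mean of the probe sets of a gene, array weights, only the groups compared, the replicate number as a block, a 2-fold threshold, robust moderation, moderation without a trend, and each array left out in turn. Alternatives added after seeing the data were the blocked fit, the block without matched controls, the blocked fit without the array labelled Ihh KO 4, matched controls averaged, fits within 1 set of arrays, and a fit without DKO 1 and DKO 3.

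The fits were tested on simulated log2 values of the genes past the filter. These were made from the control values of each set, the spread of the real values and the matched controls. The pseudocount, the filter, the choice of probe sets and the matching of controls were not part of that test. For DKO against control, the fit of group means called 38.8 percent of 67 genes changed 1.5-fold, 82.1 percent of 67 changed 2-fold and 100 percent of 66 changed 4-fold, and 33 of its 180 calls were of unchanged genes. The blocked fit called 38.8, 80.6 and 97.0 percent, and 6 of its 150 calls were of unchanged genes. The number of arrays limits the precision, and the signals carry no counts. The labels do not say that the arrays of a group came from separate animals, so p-values measure the spread between these arrays, which can be technical.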

Results

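Gene expression was compared across 19 arrays of mouse ovary RNA: 8 from controls heterozygous for Dhh and Ihh, 4 labelled Dhh KO, 4 labelled Ihh KO and 3 from ovaries lacking both genes (DKO). Dhh and Ihh encode Desert and Indian hedgehog, secreted ligands of the Hedgehog pathway. The comparisons ask what each ligand, and the pair together, contributes to gene expression in the adult ovary. Signals shared a trimmed mean of 500 on every array, and the median signal per array lay between 101 (control 4) and 159.8 (control 6). The hybridization controls split the arrays into a first set (controls 1 to 4 and all DKO arrays) and a second set (controls 5 to 8 and all single knockouts). The ratio of the 3' to the 5' BioC control was 0.987 to 1.06 in the first set and 0.685 to 0.781 in the second. Between the control arrays of the sets 3067 genes differed (limma, adjusted p under 0.05), or 6574 with controls paired by the source they appear to share. Control levels are therefore given for the set that holds the mutant arrays. Changes in the fit of group means are against all 8 controls and so can differ from the ratio of the levels printed beside them. Each comparison is also given from the blocked fit, which keeps the sets apart. The 3'/5' signal ratio of Gapdh, a measure of RNA integrity, was 1.94 ± 0.0534 (SD, n = 4) in controls of the second set, 2.52 ± 0.311 (n = 4) in Dhh KO and 2.07 ± 0.215 (n = 4) in Ihh KO. It was 1.75 ± 0.0506 (n = 4) in controls of the first set and 1.72 ± 0.0556 (n = 3) in DKO.

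The targeted genes were read first, on every array. Dhh had a signal of 606 to 1371 on the 8 controls, 5.14 to 25.4 on the 4 Dhh KO arrays and 3.85 to 14.2 on the 3 DKO arrays. It was 527 to 709 on Ihh KO 1 to 3. On the array labelled Ihh KO 4 it was 2.96, which goes against that label. These are values of the stronger of its probe sets, which is the one tested. The weaker read 34.7 to 104 on the controls, 7.84 to 63.5 in Dhh KO, 27.8 to 38.9 in DKO, 41.9 to 68.1 on Ihh KO 1 to 3 and 46.9 on the array labelled Ihh KO 4. Its readings in DKO, where Dhh is deleted, overlap the controls, so it does not settle that label. Ihh lay between 139 and 425.5 on the controls and averaged 139.9 ± 24.8 (SD, n = 4) in Dhh KO. It averaged 30.3 ± 16.0 (n = 3) on Ihh KO 1 to 3 and 46.9 ± 9.15 (n = 3) in DKO, and read 108 on the array labelled Ihh KO 4. The group was kept as labelled in the fit of group means, and the blocked fit was also run without that array.

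Transcripts of Hedgehog target genes were low in DKO, and Hhip was low on Ihh KO 1 to 3 as well. Hhip, a membrane protein that binds and restrains Hedgehog ligands, averaged 175 ± 73.5 (SD, n = 4) in controls of the first set, 238 ± 36.6 (n = 4) in controls of the second and 229.8 ± 39.7 (n = 4) in Dhh KO. It averaged 25.5 ± 21.5 (n = 3) on Ihh KO 1 to 3 and 14.4 ± 2.93 (n = 3) in DKO. Ptch1, the Hedgehog receptor and a target of the pathway, averaged 3904 ± 118, 4488 ± 414, 5105 ± 335, 3253 ± 317 and 2204 ± 153 in the same order. Gli1, a transcription factor induced by Hedgehog signalling, averaged 122 ± 33.4, 60.1 ± 31.9, 74.7 ± 9.11, 33.9 ± 15.3 and 7.33 ± 5.18. Gli1 lay under the filter and was not tested. The Hedgehog target list with its 2 tested genes was too short for a list test. The array labelled Ihh KO 4 read 105 for Hhip, 4292 for Ptch1 and 65.5 for Gli1.

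**Figure D1:**
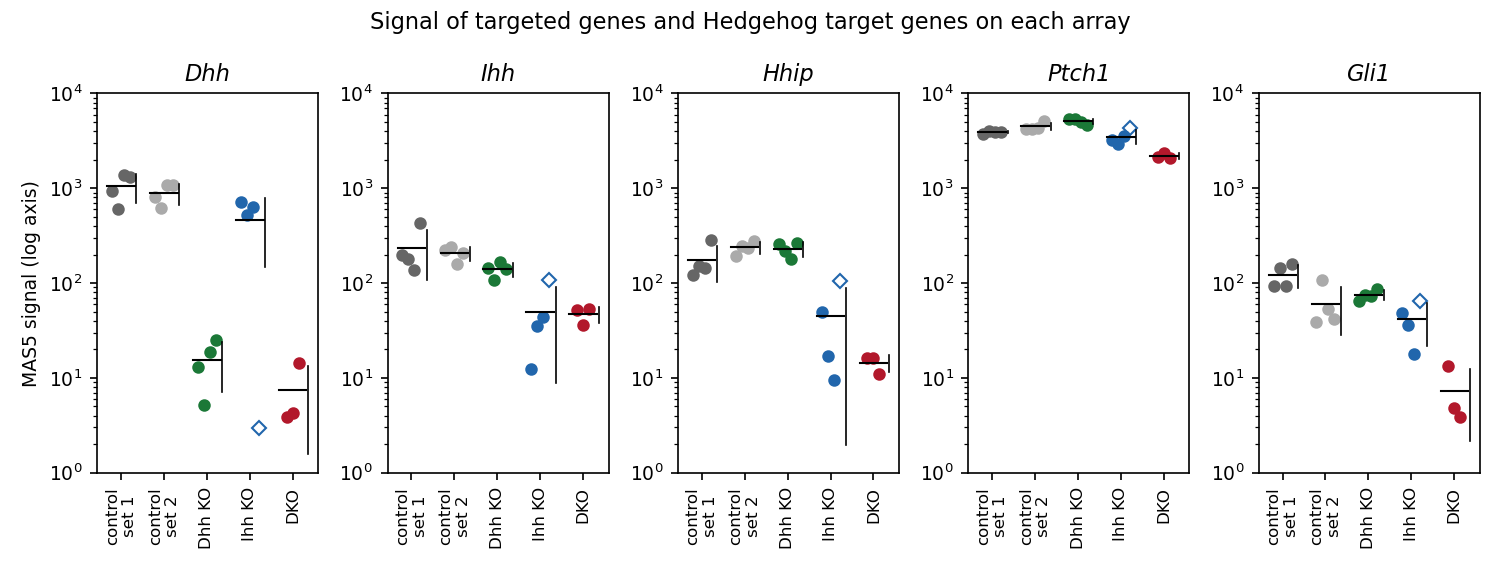
Signal (MAS5, log scale) of Dhh, Ihh, Hhip, Ptch1 and Gli1 on each of the 19 arrays, with 1 point per array, the group mean as a line and the SD as a bar; controls are drawn by set, and the array labelled Ihh KO 4, an open diamond, is part of the Ihh KO mean. Dhh was 2.96 on that array, against 527 to 709 on Ihh KO 1 to 3.

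In Dhh KO, Dhh itself fell most. It fell by 5.47 on the log2 scale (SE 0.77, limma adjusted p = 0.009), from 898 ± 225 (SD, n = 4) in controls of the second set to 15.6 ± 8.57 (n = 4). The Hedgehog targets did not pass the test: Ptch1 stood at a log2 change of 0.29 (adjusted p = 0.12) and Hhip at 0.19 (adjusted p = 0.81). The weaker probe sets of Ptch1 moved apart, 1 reading 122 to 154 in Dhh KO against 43.0 to 67.6 in controls of the second set and the other 149.8 to 202 against 219.9 to 237. Ihh stood at -0.58 (adjusted p = 0.35). In the fit of group means 19 genes were called, 6 higher and 13 lower. The rises included Akap9, a scaffold protein of the centrosome and Golgi, from 1917 ± 225 to 2680.2 ± 261 (log2 change 0.67 against all 8 controls, adjusted p = 0.045; 0.48 in the blocked fit). Rises of the same adjusted p were found in Tmem245 (0.65), Paf1, a subunit of a transcription elongation complex (0.57), Kdm2a, a histone demethylase (0.45), and the splicing factor Sf3b1 (0.28). The falls included Scand1 from 202 ± 13.6 to 115 ± 15.9 (-1.28 against all 8 controls, adjusted p = 0.045; -0.79 in the blocked fit), Wfdc6a (-1.23), Psmb9, an immunoproteasome subunit (-0.78), and Yif1b (-0.74). Lower too were Serhl (-0.73), the lipid droplet protein Hilpda (-0.73), Dbnl (-0.73), Bnip1 (-0.70) and Yif1a (-0.66).

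The blocked fit made none of these calls, although the named changes kept their direction, with Serhl at -0.63, Bnip1 at -0.79 and Sf3b1 at 0.24. A fit within the second set called 1 gene, Dhh. The Dhh KO arrays, on which they rest, had Gapdh 3'/5' ratios of 2.08 to 2.79. The blocked fit called 0 genes in Dhh KO (limma, 1092 at an unadjusted p under 0.05), with Dhh at -5.37 (adjusted p = 0.11). It called Dhh alone when the array labelled Ihh KO 4, which carries almost no Dhh signal, was left out (adjusted p = 6.4e-09). None of the 18 lists was called in Dhh KO. In the fit of group means the endothelial genes came nearest, with a median log2 change of 0.31 (adjusted p = 0.052), together with the macrophage genes, all 10 of which lay lower (median -0.34, adjusted p = 0.052). The medians in the blocked fit were 0.19 (adjusted p = 0.097) and -0.24 (adjusted p = 0.082).

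Hhip was lower in Ihh KO. On the arrays whose Dhh signal fits their label, a group of genes that includes Ptch1 was also called lower. With all 4 arrays the fit of group means called 3 genes, all lower: Hhip by -2.36 (SE 0.37), Ihh by -2.22 (SE 0.34) and Thap3 by -0.79 (SE 0.12), each with limma adjusted p = 0.014. Thap3 averaged 395 ± 35.4 (SD, n = 4) in controls of the second set and 219 ± 38.8 (n = 4) in Ihh KO. With all 4 arrays the blocked fit called 0 genes (limma, 1581 at an unadjusted p under 0.05). Without the array labelled Ihh KO 4 it called 61 genes, 16 higher and 45 lower, and a fit within the second set without that array called 19. Of 35 splits of these arrays into groups of the same sizes, 2 gave at least the 61 calls of the blocked fit, the real one included. Chance was therefore not excluded for that count. The values of single genes given next come from that blocked fit and Ihh KO 1 to 3.

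Serpina5, a secreted serine protease inhibitor, fell most, from 1762 ± 935 (SD, n = 4) to 224 ± 347 (n = 3; log2 change -4.17, SE 0.87, adjusted p = 0.037). Next were Hhip (-3.10, adjusted p = 3.0e-04), the glycosyltransferase Mgat4c (-2.95, adjusted p = 0.022), Klhl14 (-2.65, adjusted p = 0.0056) and Ihh (-2.62, adjusted p = 0.0048). The plasma membrane calcium pump Atp2b3 fell from 269 ± 109.9 to 42.7 ± 34.9 (-2.62, adjusted p = 0.0093). Smpx, a small protein of striated muscle, fell from 497 ± 43.0 to 90.0 ± 37.1 (-2.44, SE 0.24, adjusted p = 1.2e-04). Stc1, a secreted glycoprotein hormone, fell from 539 ± 235 to 88.9 ± 8.90 (-2.36), the zinc transporter Slc30a2 from 349.9 ± 91.2 to 79.4 ± 63.8 (-2.26) and Bpifb1 from 266 ± 80.7 to 61.7 ± 39.5 (-2.18). Ptch1 fell by 0.46 (adjusted p = 0.035). Among the rises were Tlcd4 from 211 ± 193 to 1391 ± 618 (3.03, adjusted p = 0.047) and Tcim from 879 ± 190.4 to 2229 ± 292 (1.35, adjusted p = 0.011). Amigo1 (1.74), Gas2 (1.57), Cyyr1 (1.54), Ehd3 (1.10), Slc35e2 (0.96) and Tpm4 (0.69) rose as well.

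Genes of cholesterol synthesis and uptake were higher on Ihh KO 1 and Ihh KO 2. Their median log2 level against controls of the set was 1.02 on Ihh KO 1, 1.48 on Ihh KO 2, 0.16 on Ihh KO 3 and -0.14 on the array labelled Ihh KO 4, against -0.21 to 0.24 on those controls. On Dhh KO 1 to 4, of the same set, it was 0.34, 0.71, 0.03 and -0.28. In the fit of group means 13 of the 14 tested members were higher (median 0.60, camera adjusted p = 2.8e-07, and adjusted p = 0.34 with an estimated correlation). Of these, 0 were called over all genes (limma) and 6 adjusted over the list alone. In the blocked fit without the array labelled Ihh KO 4 the median was 0.89 (adjusted p = 2.3e-13), with 2 members called and 13 adjusted over the list alone. Ebp, a sterol isomerase, rose by 0.80 (adjusted p = 0.016), and the sterol desaturase Sc5d rose from 1549 ± 221 (SD, n = 4) to 3264 ± 1350.1 (n = 3; 1.00, adjusted p = 0.048). Fdps (1.34, adjusted p = 0.077) and Nsdhl (1.00, adjusted p = 0.11), enzymes of the same pathway, did not pass over all genes.

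Other lists moved in Ihh KO with no member called over all genes. In the fit of group means, surface epithelium genes were higher (9 of 9, median 0.35, camera adjusted p = 3.3e-04, and adjusted p = 0.12 with an estimated correlation), with 4 called adjusted over the list alone. Their median level was 0.004, 0.34 and 0.49 on Ihh KO 1 to 3, against -0.20 to 0.17 on controls of the second set. It was highest, 0.57, on the array labelled Ihh KO 4. Endothelial genes were higher (median 0.37, adjusted p = 7.5e-04, and adjusted p = 0.35 with an estimated correlation), with 3 called adjusted over the list alone. Cell division genes were lower (11 of 12, median -0.40, adjusted p = 3.3e-04, and adjusted p = 0.34 with an estimated correlation), with 7 called adjusted over the list alone. Smooth muscle genes were lower (12 of 13, median -0.45, adjusted p = 0.0046, and adjusted p = 0.48 with an estimated correlation), a call the blocked fit did not make (adjusted p = 0.12). Immediate early genes were higher (median 0.42, adjusted p = 0.042, and adjusted p = 0.34 with an estimated correlation; blocked adjusted p = 0.054). In the same directions, the blocked fit called the surface epithelium (adjusted p = 6.2e-04), endothelial (adjusted p = 0.013) and cell division (adjusted p = 5.5e-04) lists. It called 2, 0 and 1 of their members adjusted over the list alone. The cell division list had a median of -0.61 on Ihh KO 3 and -0.20, -0.23 and -0.02 on the arrays labelled Ihh KO 1, 2 and 4, against 0.26 on control 8 and -0.09 to -0.06 on the other controls of that set. With the array labelled Ihh KO 4 left out, the endothelial list was not called there (adjusted p = 0.078) and the immediate early list was (median 0.53, adjusted p = 0.023). Macrophage genes were called in the blocked fit with all arrays (median 0.32, adjusted p = 0.040) and not without the array labelled Ihh KO 4 (adjusted p = 0.11). The corpus luteum genes were called in the blocked fit without that array (median 1.72, adjusted p = 0.025), with 0 members called by limma. Their mean level swung from -2.07 (control 8) to 1.49 (control 6) among controls of the second set and was at most 1.90 on Ihh KO 1 to 3 and at most 1.18 in Dhh KO. The blocked list tests were not run with an estimated correlation.

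In DKO 594 genes were called, 316 higher and 278 lower, and 134 of the higher and 151 of the lower genes changed at least 2-fold. Dhh fell by 6.10 on the log2 scale (adjusted p = 4.2e-04) and Ihh by 2.03 (adjusted p = 0.003). With them fell Hhip by 3.27 (SE 0.41, adjusted p = 1.3e-04) and Ptch1 by 0.92 (SE 0.10, adjusted p = 4.1e-05). With the sets kept apart 406 genes were called, 202 higher and 204 lower, of which 315 were among the 594. A fit within the first set called 79. With the set as a block and controls unmatched, DKO vs control gave 374 calls and Dhh KO vs control 0. The gap was smaller with matched controls averaged (1011 and 811) and reversed with the replicate number as a block (363 and 3689), and neither of these fits keeps the sets apart.

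The largest falls in DKO beyond Dhh included a protease inhibitor, a calcium pump and transcription factors. Serpina5 averaged 1745 ± 943 (SD, n = 4) in controls of the first set and 98.0 ± 104 (n = 3) in DKO (log2 change -4.31, adjusted p = 0.0066). Atp2b3 fell from 524 ± 236 to 13.7 ± 8.40 (-4.19, adjusted p = 9.8e-04), and the zinc finger transcription factor Osr2 from 816 ± 136 to 62.8 ± 5.79 (-3.51, adjusted p = 4.1e-05). Mgat4c fell from 167 ± 113 to 10.1 ± 6.87 (-3.35), and the T-box transcription factor Tbx3 from 1179 ± 477 to 126 ± 49.9 (-3.25, adjusted p = 5.1e-04). The laminin chain Lamc3 fell from 239.7 ± 76.1 to 22.2 ± 4.42 (-2.92, adjusted p = 3.9e-05), and Bpifb5 from 376 ± 204 to 40.3 ± 18.0 (-2.76). The transcription cofactor Vgll3 fell from 1029.9 ± 683 to 176 ± 42.3 (-2.58). All of these were also called in the blocked fit, with Osr2 at -3.55 (adjusted p = 4.7e-04) and Lamc3 at -3.03 (adjusted p = 1.3e-04).

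The largest rises in DKO were Plet1, from 111 ± 93.9 (SD, n = 4) to 1877 ± 1616 (n = 3; log2 change 3.47, adjusted p = 0.0023), and Wfdc2, a secreted epithelial protein, from 69.8 ± 10.1 to 843 ± 786 (2.86, adjusted p = 0.0014). On DKO 1, DKO 2 and DKO 3 Plet1 read 1949, 227 and 3456 and Wfdc2 699, 139 and 1691, in the order of the oviduct glycoprotein Ovgp1 (3730, 53.6 and 4679). The mast cell proteases Cma1 (61.6 ± 19.2 to 701 ± 659; 2.63, adjusted p = 0.0071) and Tpsb2 (43.7 ± 11.0 to 449 ± 382; 2.50, adjusted p = 0.009) rose. So did Tac1, the precursor of substance P (2.29), the transcriptional coactivator Eya4 (2.26), the secreted semaphorin Sema3e (2.24), the secreted Wnt antagonist Frzb (2.18), Tafa4 (2.09) and Gcnt1 (2.07). All 10 were called in the blocked fit, with Plet1 at 3.60 (adjusted p = 0.0046) and Sema3e at 2.48 (adjusted p = 0.0019).

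Some steroidogenic and contractile genes fell in DKO. Of 7 tested theca genes all were lower and 3 fell (median -0.80, camera adjusted p = 1.9e-05, and adjusted p = 0.051 with an estimated correlation). Another 3 genes of the list, Lhcgr, Insl3 and Fdxr, had no single-gene probe set. RNA of whole ovaries does not show in which cells these genes fell. The median level of the theca list was -0.65 on DKO 1, -0.93 on DKO 2 and -1.82 on DKO 3, against -0.21 to 0.14 on controls of the first set. Star, which brings cholesterol into mitochondria, fell from 5699 ± 1272 (SD, n = 4) to 1897 ± 1089.9 (n = 3; -1.82, adjusted p = 0.0013). Cyp11a1, which makes pregnenolone from it, fell from 9818 ± 2879 to 3999.7 ± 2607 (-1.37, adjusted p = 0.033), and Fdx1, the electron donor of that step, fell from 11795 ± 1814 to 6574 ± 1283 (-0.68, adjusted p = 0.0052). Scarb1, a lipoprotein receptor, stood at -0.80 (adjusted p = 0.20). Cyp17a1, the androgen-forming enzyme, chosen after its values were seen, stood at 315 ± 245 against 3825 ± 4228 (adjusted p = 0.37). Of 13 smooth muscle genes 8 fell, or 9 adjusted over the list alone (median -1.02, adjusted p = 1.5e-09, and adjusted p = 0.16 with an estimated correlation). They included Myh11, smooth muscle myosin, from 2495 ± 567 to 762 ± 496 (-2.07, adjusted p = 0.0013). Others were Actg2, smooth muscle actin (-2.12, adjusted p = 0.0027), Myl9, a myosin light chain (-1.08, adjusted p = 0.0027), and Tpm2, a tropomyosin (-1.02, adjusted p = 3.0e-04). The median level of the smooth muscle list was -0.33 on DKO 1, -1.74 on DKO 2 and -1.13 on DKO 3, against -0.14 to 0.21 on controls of the first set.

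Some stromal and vascular genes fell as well. Of 17 fibroblast and matrix genes 2 fell, or 5 adjusted over the list alone (median -0.39, adjusted p = 4.6e-04, and adjusted p = 0.46 with an estimated correlation). The median level of the list was -0.26 on DKO 1, -0.35 on DKO 2 and -1.02 on DKO 3, against -0.30 on control 4. Nr2f2, a nuclear receptor, fell from 5427 ± 317 (SD, n = 4) to 3178 ± 502 (n = 3; -0.61, adjusted p = 0.0094), and Mfap5, a microfibril protein, fell by 1.02 (adjusted p = 0.013). Of 11 endothelial genes 5 fell, or 6 adjusted over the list alone (median -0.54, adjusted p = 1.9e-05, and adjusted p = 0.27 with an estimated correlation). Their median level was -0.15 on DKO 1, -0.39 on DKO 2 and -0.64 on DKO 3, against -0.14 on control 1. The sialomucin Emcn fell from 1011 ± 169 to 517 ± 129.5 (-1.09, adjusted p = 9.7e-04), as did the angiopoietin receptor Tek (-0.80, adjusted p = 0.016), the tight junction protein Cldn5 (-0.57, adjusted p = 0.031) and Vwf (-0.95, adjusted p = 0.037). In the blocked fit 3 theca, 7 smooth muscle, 4 fibroblast and 2 endothelial genes fell, while Tek and Vwf were not called (adjusted p = 0.091 and 0.0503). All of these lists were called there at the preset correlation, with camera adjusted p of 5.9e-10, 8.8e-17, 1.1e-09 and 3.1e-05. Like every list test of the blocked fit, these were not run with an estimated correlation. In the fit of group means none of these lists was called with an estimated correlation.

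Surface epithelium genes rose in DKO, all 9 being higher and 6 called (median 1.10, camera adjusted p = 8.9e-08, and adjusted p = 0.0078 with an estimated correlation). Cdh1, the epithelial cadherin, rose from 207 ± 52.5 (SD, n = 4) to 813 ± 359 (n = 3; 1.83, adjusted p = 1.3e-04). The keratins rose too, Krt18 from 719.6 ± 153 to 1921 ± 634 (1.47, adjusted p = 2.0e-04) and Krt8 from 864 ± 173 to 1757 ± 385 (1.16, adjusted p = 5.7e-04), and the transcription factor Wt1 rose from 1244 ± 196 to 2111 ± 188 (0.72, adjusted p = 0.0034). In the blocked fit 4 members were called, or 8 adjusted over the list alone (adjusted p = 1.1e-12). Ovgp1 and adipocyte genes were high on DKO 1 and DKO 3. The oviduct list, with 3 tested members, had a median of 0.20 and a mean of 1.91 on DKO 1, -0.28 and -0.37 on DKO 2, 1.62 and 2.67 on DKO 3, and 0.13 and 0.85 on control 1. Ovgp1, an oviduct glycoprotein, read 3730 and 4679 there and 53.6 on DKO 2, against 128 ± 187 (SD, n = 4) in controls of the first set. The adipocyte hormone Adipoq, chosen after its values were seen, read 1247, 2301 and 34.9 on DKO 1, DKO 3 and DKO 2. With DKO 1 and DKO 3 left out, 63 genes were called in DKO.

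Macrophage, oocyte and cholesterol lists were also called in DKO. Macrophage genes were higher (9 of 10, median 0.57, adjusted p = 0.014, and adjusted p = 0.54 with an estimated correlation). The scavenger receptor Cd163 fell from 224 ± 71.3 (SD, n = 4) to 73.9 ± 39.5 (n = 3; -1.89, adjusted p = 0.0033). C1qc (0.80), C1qa (0.70) and Cd68 (0.85) did not pass over all genes. Oocyte genes were higher as a list with 0 members called by limma (median 0.53, adjusted p = 0.0044, and adjusted p = 0.54 with an estimated correlation). Cholesterol genes were lower (13 of 14, median -0.29, adjusted p = 0.0049, and adjusted p = 0.54 with an estimated correlation), with Sc5d at 815 ± 127 against 1478 ± 243 (-0.89, adjusted p = 0.043). Some genes were called on lists that were not. They were Pdpn of the lymphatic list (0.65, adjusted p = 0.024; blocked adjusted p = 0.12), Sox9 of the Sertoli list (1.26, adjusted p = 0.028; blocked adjusted p = 0.13) and Alas2 of the erythroid list (1.26, adjusted p = 0.0078; blocked adjusted p = 0.030).

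The remaining lists were not called in DKO. Their median log2 changes were 0.05 for Hedgehog pathway components (adjusted p = 0.60), 0.23 for granulosa genes (adjusted p = 0.062), -0.58 for corpus luteum genes (adjusted p = 0.36), 0.14 for ovulation genes (adjusted p = 0.99) and -0.14 for lymphatic genes (adjusted p = 0.96). They were 0.54 for Sertoli genes (adjusted p = 0.57), 0.10 for cell division genes (adjusted p = 0.20) and 0.40 for oviduct genes (adjusted p = 0.091). Adipocyte genes had a median of 1.29 (adjusted p = 0.13) and immediate early genes of 0.22 (adjusted p = 0.57). For the ovulation and lymphatic lists the test pointed the other way than the median. The lymphocyte, adrenal cortex and erythroid lists had 0, 1 and 2 tested members and were not tested.

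**Figure D2:**
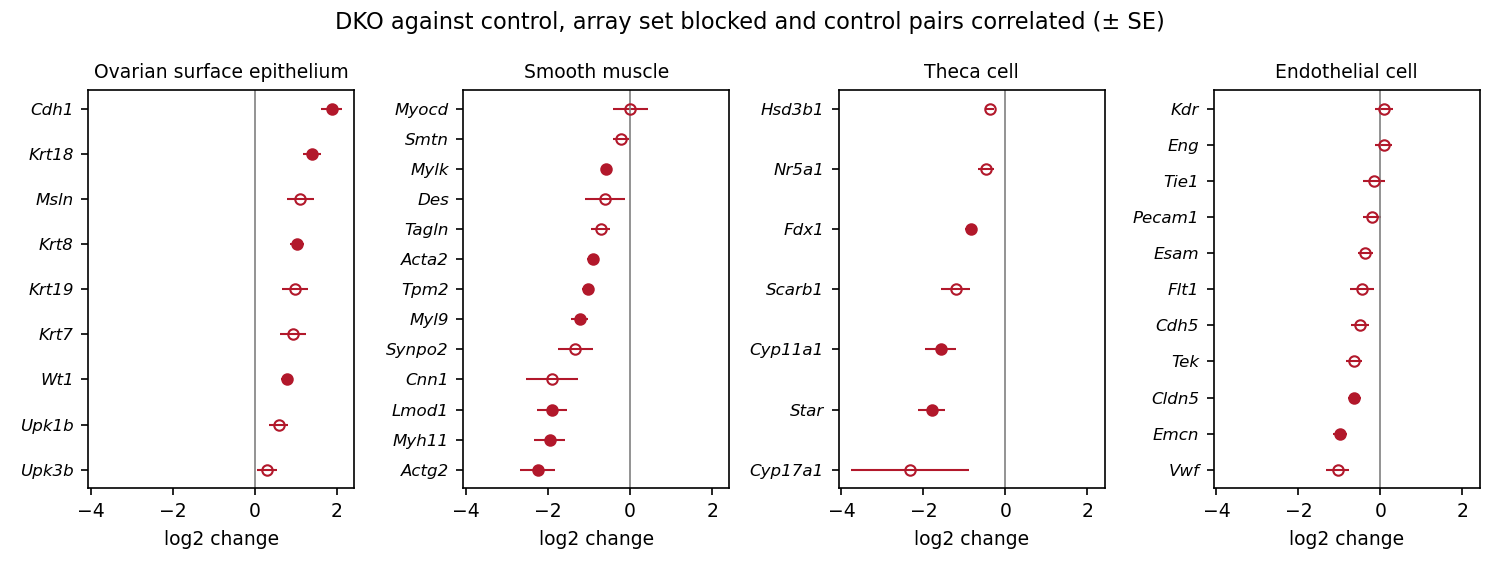
Log2 change in DKO against control from the blocked fit for tested members of gene lists, with 1 point per gene and the SE as a bar; filled points have an adjusted p under 0.05. The median change was -1.03 for smooth muscle genes, -1.21 for theca genes and 0.98 for surface epithelium genes.

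DKO was set against each single knockout to ask what the second deletion adds. Against Dhh KO, Hhip (-3.46, adjusted p = 2.5e-04), Osr2 (-3.52, adjusted p = 1.6e-04) and Atp2b3 (-4.02, adjusted p = 0.002) were lower in DKO. Wfdc2 (3.30, adjusted p = 9.7e-04) and Plet1 (3.22, adjusted p = 0.0043) were higher, and all 5 were called in the blocked fit too. Ovgp1, at 2821 ± 2443 (SD, n = 3) in DKO and 32.0 ± 10.4 (n = 4) in Dhh KO, and Dynlrb2, a dynein light chain, were higher (4.74 and 3.34; blocked adjusted p = 0.034 and 0.030). Bhmt, an enzyme of betaine metabolism (-4.34), the acute phase protein Saa1 (-3.41) and the calcium-binding protein S100b (2.92) were called in the fit of group means and not in the blocked fit (adjusted p = 0.062, 0.064 and 0.22). The fit of group means called 3220 genes, 2014 higher and 1206 lower, and the blocked fit 672, 407 higher and 265 lower, with 477 in common. With the set as a block and controls unmatched, 75 genes were called. Of the 3220 calls 88.7 percent lay on the side to which the controls of the sets differed.

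The list tests of DKO against Dhh KO use the same DKO arrays as those against control, so calls shared with them are not independent. Endothelial genes were lower (8 of 11 called, camera adjusted p = 7.9e-05, and adjusted p = 0.37 with an estimated correlation). So were theca (3 of 7, adjusted p = 0.002, and adjusted p = 0.24 with an estimated correlation), smooth muscle (6 of 13, adjusted p = 6.1e-04, and adjusted p = 0.57 with an estimated correlation) and cholesterol genes (4 of 14, adjusted p = 0.0047, and adjusted p = 0.63 with an estimated correlation). Surface epithelium genes were higher (7 of 9 called, adjusted p = 7.9e-05, and adjusted p = 0.061 with an estimated correlation), as were macrophage genes (5 of 10, adjusted p = 0.005, and adjusted p = 0.57 with an estimated correlation). Oocyte (adjusted p = 0.046) and cell division genes (adjusted p = 0.049) were also called higher, both at adjusted p = 0.63 with an estimated correlation. Neither was called in the blocked fit (adjusted p = 0.31 and 0.060). That fit called the other lists too, with 4 of 11 endothelial, 5 of 7 theca, 7 of 13 smooth muscle, 1 of 14 cholesterol, 5 of 9 surface epithelium and 1 of 10 macrophage genes called. It also called the fibroblast list lower (4 of 17, adjusted p = 1.5e-06).

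Against Ihh KO, DKO had more Nppc, the precursor of C-type natriuretic peptide (2377 ± 539, SD, n = 3, against 439 ± 110.0, n = 4; log2 change 2.43, adjusted p = 6.6e-04). It also had more Eya4 (2.90, adjusted p = 0.0023), Wfdc2 (2.64, adjusted p = 0.0051) and Dynlrb2 (3.37, adjusted p = 0.011), and all 4 were called in the blocked fit. Dhh (-4.01, adjusted p = 0.01), Bhmt (-4.92, adjusted p = 0.014) and Plekhg4 (-3.49, adjusted p = 0.037) were lower in both fits. Dhh stood at -5.71 in the blocked fit (adjusted p = 1.9e-07) without the array labelled Ihh KO 4, which carries almost no Dhh signal. Ecrg4 (2.66), Saa1 (-3.52) and the Wnt ligand Wnt10b (-3.39) were not called in the blocked fit (adjusted p = 0.30, 0.054 and 0.077). There were 2562 calls, 1648 higher and 914 lower, and 697 in the blocked fit, 403 higher and 294 lower, of which 374 were shared. With the set as a block and controls unmatched, 49 genes were called. Of the 2562, 87.0 percent lay on the side to which the controls of the sets differed. Without the array labelled Ihh KO 4 there were 604 calls in the blocked fit.

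Cholesterol genes were lower in DKO than in Ihh KO (6 of 14 called, camera adjusted p = 2.0e-06, and adjusted p = 0.47 with an estimated correlation). So were endothelial genes (8 of 11, adjusted p = 2.3e-06, and adjusted p = 0.35 with an estimated correlation), theca genes (3 of 7, adjusted p = 0.0013, and adjusted p = 0.35 with an estimated correlation) and smooth muscle genes (5 of 13, adjusted p = 0.0019, and adjusted p = 0.47 with an estimated correlation). Oocyte genes (6 of 16, adjusted p = 0.0013) and cell division genes (6 of 12, adjusted p = 0.0027) were higher, both at adjusted p = 0.47 with an estimated correlation. Surface epithelium genes were higher (4 of 9, adjusted p = 0.027, and adjusted p = 0.38 with an estimated correlation). The blocked fit called these lists with fewer members for most: 5 cholesterol, 3 endothelial, 5 theca, 7 smooth muscle, 1 oocyte, 1 cell division and 1 surface epithelium genes. It also called the fibroblast list lower (5 of 17, adjusted p = 3.5e-07).

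Between the single knockouts the fit of group means and the blocked fit each called 0 genes with all 4 arrays labelled Ihh KO (limma, 939 and 1363 at an unadjusted p under 0.05). Without the array labelled Ihh KO 4 the blocked fit called 47 genes, 13 higher and 34 lower in Ihh KO. The lower genes included Hhip (-3.05, adjusted p = 2.6e-04), Smpx (-2.40, adjusted p = 7.5e-05), Atp2b3 (-2.92, adjusted p = 0.0057), Tmem200a (-2.57, adjusted p = 0.016), Ihh (-2.07, adjusted p = 0.023) and Ptch1 (-0.65, adjusted p = 0.0053). The higher genes included Dhh (4.88, adjusted p = 1.2e-07), Tlcd4 (3.24, adjusted p = 0.039), Amigo1 (1.67), Cyyr1 (1.46) and Ebp (0.85, adjusted p = 0.018). In the fit of group means, surface epithelium genes were higher in Ihh KO than in Dhh KO (9 of 9, median 0.44, camera adjusted p = 7.6e-07, and adjusted p = 0.012 with an estimated correlation). So were macrophage genes (10 of 10, adjusted p = 4.6e-06, and adjusted p = 0.28 with an estimated correlation), cholesterol genes (14 of 14, adjusted p = 8.1e-05, and adjusted p = 0.53 with an estimated correlation) and immediate early genes (5 of 7, adjusted p = 0.024, and adjusted p = 0.28 with an estimated correlation). These list tests include the array labelled Ihh KO 4. Against controls of its set, surface epithelium genes had a median of 0.57 there and macrophage genes 0.43. On Ihh KO 1 to 3 the medians were 0.004, 0.34 and 0.49 for surface epithelium and -0.29, 0.45 and 0.56 for macrophage genes.

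Non-additivity asks whether the change in DKO differed from the sum of both single changes. Dynlrb2 (4.32, blocked adjusted p = 0.049) and Wfdc2 (3.09, blocked adjusted p = 0.049) lay above the sum in both fits. On DKO 1, DKO 2 and DKO 3 Wfdc2 followed the order of Ovgp1 (3730, 53.6 and 4679). For Wfdc2, oviduct tissue on these arrays and a joint effect of both losses were therefore not told apart. Bhmt (-6.09), Tnfrsf9 (-4.81), Wnt10b (-4.71), Saa1 (-4.59) and Ccn5 (-4.48) lay below the sum, and Ovgp1 (4.32), Gpha2 (3.36) and S100b (3.32) above it, in the fit of group means alone. Their blocked adjusted p lay between 0.066 and 0.42. That fit called 3608 genes, 2287 above and 1321 below the sum, and the blocked fit 415, 275 above and 140 below, of which 241 were shared. Unchanged simulated arrays with the real set difference gave 3603 calls in the fit of group means and 0 in the blocked fit. Without the array labelled Ihh KO 4 the blocked fit called 274, among them Eya4 (4.41, adjusted p = 0.016), Plch2 (-3.67, adjusted p = 0.031), Plin4 (-5.44, adjusted p = 0.033) and Lipg (-5.05, adjusted p = 0.037). Endothelial (8 of 11 below the sum) and cholesterol genes (6 of 14 below) were called as lists in the fit of group means (adjusted p = 3.0e-05 and 3.3e-05, and adjusted p = 0.55 for both with an estimated correlation). Theca genes lay below (adjusted p = 0.017, and adjusted p = 0.55 with an estimated correlation), and cell division genes (adjusted p = 0.0073, and adjusted p = 0.55 with an estimated correlation) and oocyte genes (adjusted p = 0.021, and adjusted p = 0.67 with an estimated correlation) above it. The blocked fit did not call the oocyte list (adjusted p = 0.28). It called the endothelial (3 of 11 members), cholesterol (2 of 14), theca (5 of 7) and cell division (1 of 12) lists, as well as smooth muscle (adjusted p = 1.6e-04) and fibroblast genes (adjusted p = 1.2e-04) below the sum and surface epithelium genes (adjusted p = 0.0045) above it.

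Some genes were called in both Ihh KO and DKO. In the fit of group means Hhip and Ihh were called in both, against 0.0674 genes for independent lists. Dhh alone was called in both Dhh KO and DKO (0.445 for independent lists), and 0 genes were called in both single knockouts (0.00315 for independent lists). With the 8 controls split at random between the comparisons the counts were 28, 5 and 0. That split took no account of the sets, so their difference can enter these counts. In the blocked fit without the array labelled Ihh KO 4, 34 of the 61 genes called in Ihh KO were called in the same direction in DKO. The number was 1.09 for independent lists. A fit without the block gave 4. It set each group against fewer control arrays, from sources not shared between the comparisons. With fewer controls that fit can call fewer genes, so its 4 is no reference for the 34. Unchanged simulated groups shared 0 calls in the fit of group means and in the blocked fit, but with 0 genes called in them (limma) they say nothing about the sharing. The 34 genes included Serpina5 (-4.17 in Ihh KO and -4.29 in DKO), Mgat4c (-2.95 and -3.18), Atp2b3 (-2.62 and -4.64), Hhip (-3.10 and -3.02) and Ihh (-2.62 and -2.06). Also shared were Tbx3 (-2.01 and -3.13), Osr2 (-1.72 and -3.55), and Ptch1 (-0.46 and -0.82). The mean signals of Hhip, Ihh, Atp2b3 and Mgat4c lay under the filter signal of 69.4 in both groups, and that of Osr2 in DKO, so the size of their log2 changes is not exact and does not rank the groups.

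**Figure D3:**
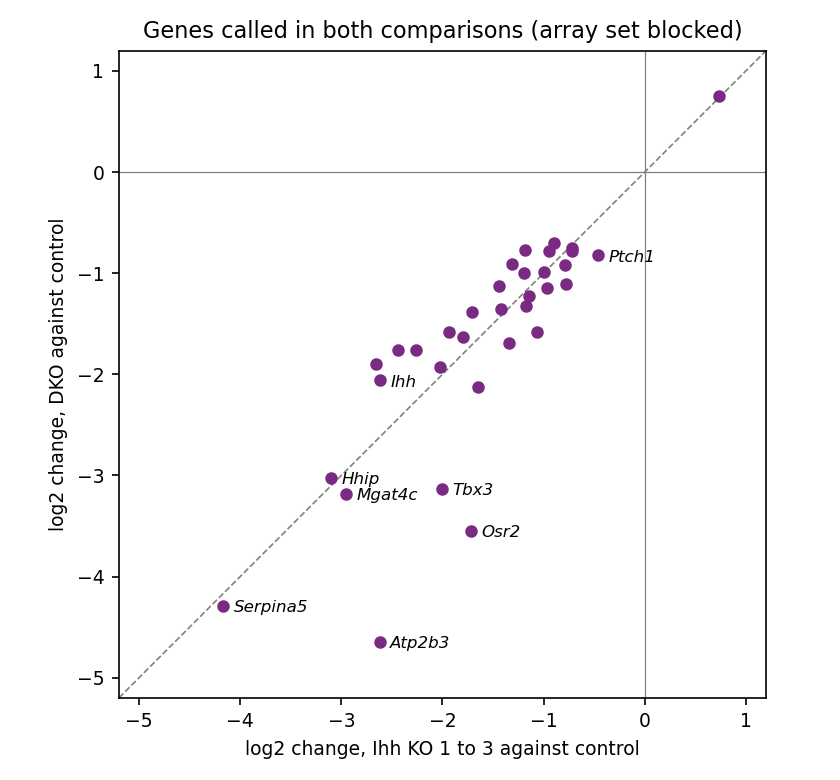
Log2 change in DKO (vertical) against log2 change in Ihh KO (horizontal) for the 34 genes called in the same direction in both by the blocked fit without the array labelled Ihh KO 4; each point is 1 gene and the dashed line marks equal change. Serpina5 lay at -4.29 in DKO and -4.17 in Ihh KO.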

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

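The tests of explanations and the other splits of the arrays given here were chosen only after the results were seen.

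The genes called between DKO and Dhh KO numbered 3220 in the fit of group means, and these groups lie on different sets of arrays. The difference between the groups correlated across genes with the difference between the control arrays of the sets (r = 0.579; 0.509 for DKO against Ihh KO), and unchanged simulated arrays with the real set difference gave 1816 calls, so the sets likely account for part of the calls. A set difference equal in mutant and control RNA does not account for all of them. The blocked fit, which gave 0 calls on the unchanged simulated arrays, called 672 genes on the real ones, 477 of them among the 3220. With the set as a block and controls unmatched the count was 75, so it depends on the matching, itself a hypothesis. The simulation assumed that matching and an equal set difference, so its 0 calls test neither. The 672 calls compare DKO with Dhh KO, which differ by the loss of Ihh, each against controls of its own set, and a difference between the sets that acted on mutant and control RNA unequally stays open.

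The array labelled Ihh KO 4 carried a Dhh signal of 2.96, against 527 to 709 on Ihh KO 1 to 3, which argues against a correct label with incomplete deletion of Ihh; a weaker Dhh probe set read 46.9 there and 41.9 to 68.1 on Ihh KO 1 to 3, but its 27.8 to 38.9 in DKO overlaps the controls (34.7 to 104), so it does not tell these apart. A swap with an array of the Dhh KO group would leave 1 array there with Dhh near the control level, and the highest Dhh signal among those arrays was 25.4 (63.5 on the weaker probe set, on Dhh KO 1, where the stronger read 13.2). Of 45 genes that separate Ihh KO 1 to 3 from Dhh KO, the array lay nearer Dhh KO on 38, or 84.4 percent, where the lowest value of a Dhh KO array was 93.3 percent. The genes were chosen with those Dhh KO arrays, which raises their values. Control arrays were not placed on these genes. The share therefore does not tell a Dhh KO origin from that of another array unlike Ihh KO 1 to 3. It lay below all Dhh KO arrays in Hhip (105 against 178 to 265) and Ptch1 (4292 against 4704 to 5421), which goes against a Dhh KO origin. Among lists chosen after their values were seen, surface epithelium genes had a median of 0.57 there and -0.42 to -0.02 in Dhh KO. Macrophage genes had 0.43 against -0.32 to -0.11. Granulosa, oocyte and cholesterol genes lay within the range of the Dhh KO arrays. A single wrong label on RNA from a Dhh KO ovary is a candidate explanation, found and tested on the same data, and an exchange with a sample outside the series stays open.

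The surface epithelium genes rose in DKO by a median of 0.98 on the log2 scale in the blocked fit (spread of the median 0.191). A smaller share of the cells whose genes fell would raise the genes of every other cell type alike. The granulosa genes had a median of 0.19 (spread 0.0817), below that of the surface epithelium by more than the spreads. These spreads are over the genes of a list, which are not independent replicates. On DKO 1, 2 and 3 the granulosa medians were 0.12, 0.11 and 0.49. Macrophage genes had 0.48, 0.79 and 0.18 there, and oocyte genes -0.01, 0.35 and 0.75. A part of the rise by this cause therefore stays open. Oviduct tissue on the DKO ovaries could add epithelial transcripts, since Ovgp1 was high on DKO 1 and DKO 3, though the oviduct list had a median of 0.20 on DKO 1 against 0.13 on control 1 (means 1.91 and 0.85). On DKO 2, where Ovgp1 read 53.6, the median of the surface epithelium genes against controls of the first set was 1.05 (0.77 on DKO 1 and 1.34 on DKO 3). With 1 such array this explanation and a change in the ovary that follows from the loss of both genes cannot be told apart.

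Other results stood out by rules fixed in advance. The Ihh signal of control 4, 425.5, and the Ptch1 signal of control 8, 5104, lay far from the other controls, taken over both sets. In this way 90 groups of values were examined, 2 stood out, and chance alone gives about 1 in 20. The effect of losing both genes differed from the sum of the single losses for 415 genes in the blocked fit, for 3 with the set as a block and controls unmatched, and for 52 in the blocked fit without control 5 (1018 without control 4). Among 3661 probe sets with no single gene named, which entered no comparison between groups above, 52 were called between DKO and control, 13 with the sets as a block, and 0 in either single knockout with limma.

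Other splits of the same arrays into groups of the same sizes show how often such counts arise without the real grouping. For Dhh KO against control, 5 of 100 splits gave at least the 19 real calls (highest other 964), and for Ihh KO 9 of 100 gave at least the 3 real calls (highest other 723), so chance was not excluded for either. Those highest splits grouped control arrays 1, 2, 4 and 8, called many times the real count and point to a structure among the arrays. For DKO against control 4 of 100 splits gave at least the 594 real calls. These splits mix the sets, so this share does not exclude chance. The highest, 1936, grouped control arrays 5, 6 and 8 of the second set and so follows the sets. Within the first set the real split alone of 35 gave 79 calls (highest other 14), and in the blocked fit the real split alone of 35 gave 406 (highest other 5).

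For DKO against Dhh KO the real split alone of 35 reached 3220 calls (highest other 205), and in the blocked fit 672 (highest other 1). DKO and the single knockouts lie on different sets, so every other split mixes the sets. The splits of DKO against either single knockout therefore cannot tell genotype from set. The 8 splits of these arrays that part all 3 pairs with the same number included 1 as large, the real one, with 1 call in the highest other. For DKO against Ihh KO it was 1 of 35 splits with 2562 calls (highest other 40); without the array labelled Ihh KO 4, the blocked fit gave 604 calls for the real split and 1 for the highest other, and its 10 splits are too few for a share under 0.05. Between the single knockouts all 35 splits gave at least the 0 real calls (limma; highest other 22). Without the array labelled Ihh KO 4, the real split alone of 35 gave 47 calls in the blocked fit, close to the highest other at 32. The blocked fit of Dhh KO against control gave 0 real calls, which all 35 splits reached (limma; highest other 1). For Ihh KO without the array labelled Ihh KO 4, 2 of 35 splits of the blocked fit gave at least the 61 real calls, so chance was not excluded; the highest other, 105, grouped control arrays 5, 6 and 7.

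Permuted group labels gave at least the 3608 real calls of non-additivity in 1 of 100 draws, the real one (highest other 700). That permutation mixes the sets, and unchanged simulated arrays with the real set difference gave 3603 calls, so it does not exclude the sets. In the blocked fit without the array labelled Ihh KO 4, labels permuted within each set gave at least the 274 real calls in 1 of 100 draws (highest other 26). The 3 genes shared between mutant groups, Dhh, Ihh and Hhip, were reached in 1 of 100 draws, the real one (highest other 1), but Dhh and Ihh are the deleted genes and shared by design. The 14 list tests called were reached in 43 of 100 draws (highest other 26), so for that count chance was not excluded.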

How the results depend on the processing

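The blocked fit, the set as a block, the matched controls averaged, the fits within 1 set and the fits without named arrays were chosen only after the data were seen; the other alternatives were planned. Counts in the fit of group means were 19 for Dhh KO, 3 for Ihh KO, 594 for DKO, 3220 for DKO vs Dhh KO, 2562 for DKO vs Ihh KO, 0 for Ihh KO vs Dhh KO (limma, 939 at an unadjusted p under 0.05), 3608 for non-additivity (DKO - Dhh KO - Ihh KO + control), 3 shared genes, 14 list tests and 92 named genes. No named gene or list called in a mutant group against control reversed direction under any alternative. The 67 results of named genes against control include Dhh, Ihh, Hhip and Ptch1 where they were not called. Of the 67, 61 kept their status, called or not called, with quantile normalization, 43 with median centring and 43 in the blocked fit. Of the 14 list tests 1 stayed past the threshold with an estimated correlation and 6 with fry. Probe sets under the filter, Gli1 among them, were not tested.

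Quantile normalization gave 1 call for Ihh KO vs Dhh KO. Median centring gave 1 for Dhh KO, 355 for DKO, 1065 for DKO vs Ihh KO, 1 for Ihh KO vs Dhh KO and 23 list tests. It moved the median log2 change of all genes from -0.03 to -0.19 in Dhh KO, 0.04 to 0.18 in DKO, 0.07 to 0.37 in DKO vs Dhh KO, 0.07 to 0.23 in DKO vs Ihh KO, -0.01 to 0.13 in Ihh KO vs Dhh KO and 0.10 to 0.42 in non-additivity (DKO - Dhh KO - Ihh KO + control). The share of higher calls moved with it from 31.6 percent (6 higher, 13 lower) to 0 percent (0 and 1) in Dhh KO, from 53.2 (316 and 278) to 63.4 (225 and 130) in DKO, from 62.5 (2014 and 1206) to 90.4 (2884 and 306) in DKO vs Dhh KO, from 64.3 (1648 and 914) to 79.1 (842 and 223) in DKO vs Ihh KO and from 63.4 (2287 and 1321) to 87.8 (2596 and 362) in non-additivity. No pseudocount gave 29 for Dhh KO. No filter gave 3 for Dhh KO and 24 list tests. The stricter filter, which tests fewer genes, gave 1 for Ihh KO, 0 shared genes and 45 named genes. Probe sets one by one gave 4 for Dhh KO. Array weights gave 685 for Dhh KO, 256 for Ihh KO, 1201 for DKO, 5392 for DKO vs Dhh KO, 4659 for DKO vs Ihh KO, 3 for Ihh KO vs Dhh KO and 121 shared genes. Only the groups compared gave 4 for Dhh KO, 1 for Ihh KO and 310 for DKO. The 2-fold threshold gave 3 for Dhh KO, 285 for DKO, 819 for DKO vs Dhh KO, 617 for DKO vs Ihh KO and 1580 for non-additivity. Estimated correlation gave 1 list test and fry 6. Except where fewer genes or arrays were used, the cause was not tested.

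With the replicate number as a block there were 3689 calls for Dhh KO vs control, 3345 for Ihh KO vs control, 363 for DKO vs control, 4332 for DKO vs Dhh KO, 4041 for DKO vs Ihh KO, 0 for Ihh KO vs Dhh KO, 5668 for non-additivity (DKO - Dhh KO - Ihh KO + control), 2519 in the overlap of calls between the 3 mutant groups, 16 list tests and 81 named genes. For DKO against Dhh KO, whose arrays of the same number correlated weakly, the block moved the count by less than 1.5 times. Controls 5 to 8 share no number with a mutant array, so this block sets each mutant group against controls 1 to 4 alone, which for the single knockouts lie on the other set.

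The set as a block gave 0 for Dhh KO, 374 for DKO, 75 for DKO vs Dhh KO, 49 for DKO vs Ihh KO, 3 for non-additivity (DKO - Dhh KO - Ihh KO + control), 1 shared gene and 45 named genes. The blocked fit gave 0 for Dhh KO and 0 for Ihh KO (1092 and 1581 at an unadjusted p under 0.05), 672 for DKO vs Dhh KO, 697 for DKO vs Ihh KO, 415 for non-additivity, 0 shared genes and 55 named genes. Without the array labelled Ihh KO 4 it gave 1 for Dhh KO, 61 for Ihh KO, 690 for DKO vs Dhh KO, 604 for DKO vs Ihh KO, 47 for Ihh KO vs Dhh KO, 274 for non-additivity, 35 shared genes and 61 named genes. Matched controls averaged gave 811 for Dhh KO, 238 for Ihh KO, 1011 for DKO, 4092 for DKO vs Ihh KO and 166 shared genes. Within 1 set there was 1 for Dhh KO, 0 for Ihh KO (limma, 1373 at an unadjusted p under 0.05) and 79 for DKO, and without the array labelled Ihh KO 4 there was 1 for Dhh KO, 19 for Ihh KO and 10 for Ihh KO vs Dhh KO. Without DKO 1 and DKO 3, DKO gave 63, DKO vs Dhh KO 187, DKO vs Ihh KO 27 and non-additivity 801, from a lone DKO array assumed to vary like the other groups. The cause was not tested, apart from the fewer arrays in the last fits.

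Leaving out 1 array at a time moved the counts in the fit of group means from 0 (without Dhh KO 2) to 344 (without control 8) for Dhh KO, where every array moved the count by over 1.5 times: Dhh KO 4 gave 1, Dhh KO 3 gave 10, controls 5, 6 and 7 gave 64, 83 and 145, and the others 2 to 5. Ihh KO went from 0 (without Ihh KO 1, 2 or 3) to 151 (without the array labelled Ihh KO 4), with 7 without control 6 and 8 without control 8. DKO went from 173 (without DKO 3) to 1017 (without control 4), with 293 without DKO 2. DKO vs Dhh KO went from 1626 (without DKO 3) to 3375 (without control 6), with 1717 without DKO 2 and 2040 without Dhh KO 1. DKO vs Ihh KO went from 636 (without DKO 3) to 2771 (without control 4), with 1184 without DKO 2 and 1595 without Ihh KO 2. Ihh KO vs Dhh KO went from 0 to 15 (without the array labelled Ihh KO 4), non-additivity (DKO - Dhh KO - Ihh KO + control) from 2572 (without DKO 3) to 3997 (without control 6), shared genes from 1 to 48 (without the array labelled Ihh KO 4), list tests from 14 to 21 (without DKO 2) and named genes from 50 (without DKO 3) to 91.

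In the blocked fit the same step moved DKO from 170 (without DKO 3) to 449 (without DKO 1), with 260 without DKO 2. DKO vs Dhh KO went from 297 (without DKO 2) to 1121 (without control 4), with 393 without DKO 3, 381, 423 and 430 without Dhh KO 1, 2 and 4, and 386 and 442 without controls 3 and 5. DKO vs Ihh KO went from 167 (without DKO 3) to 1339 (without control 4), with 244 without DKO 2, 281 and 446 without Ihh KO 2 and 3, and 438, 383, 422, 453 and 456 without controls 1, 2, 3, 5 and 6. Non-additivity went from 52 (without control 5) to 1018 (without control 4), with 187, 185, 177, 84, 92 and 878 without controls 1, 2, 3, 6, 7 and 8, 153, 148 and 219 without Dhh KO 1, 2 and 4, 237, 147 and 255 without Ihh KO 1, 2 and 3, 274 without the array labelled Ihh KO 4, and 148 without either DKO 2 or DKO 3. Dhh KO had 2 calls without control 8 and 1 without the array labelled Ihh KO 4, Ihh KO had 3 without control 4, 24 without control 8 and 61 without the array labelled Ihh KO 4, and Ihh KO vs Dhh KO had 47 without that array. These counts use fewer arrays.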

Other observations

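The test of the matched controls given here was chosen only after the result was seen.

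The DKO arrays differed among themselves in genes of tissues that adjoin the ovary, which were chosen after their values were seen. Foxj1, a transcription factor of ciliated cells such as those of the oviduct, read 64.4 on DKO 1, 2.54 on DKO 2 and 667 on DKO 3. Fabp4, a fatty acid carrier abundant in fat tissue, read 4536, 558 and 5651 on the same arrays. Ovgp1 and Adipoq were likewise lowest on DKO 2.

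The control arrays of the sets may come from the same 4 RNA sources. Deviations from the means of their set correlated across genes between controls 1 and 5, 2 and 6, 3 and 7, and 4 and 8, with a mean r of 0.689. Of the 24 ways to match the 4 arrays of each set this was the highest (a share of 0.0417), and the next reached 0.402. The median SD of a gene was 0.121 on the log2 scale between the arrays of a pair and 0.211 between different controls of a set. The labels do not mention shared sources, and genes are not independent replicates, so this stays a hypothesis found and tested on the same data.

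More than 1 probe set of a gene was called in opposite directions for 167 genes between DKO and Dhh KO, 45 between DKO and Ihh KO and 243 in non-additivity, and for 0 genes in the other comparisons (limma, fit of group means). No gene list was called between the control arrays of the sets, where the smallest adjusted p was 0.14, for smooth muscle genes and for fibroblast genes.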
